A study of Rattus norvegicus with 23 samples.

How the data were processed

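RNA from the area postrema, a sensory circumventricular organ of the medulla that lacks a full blood-brain barrier, was measured on Affymetrix Rat Genome 230 2.0 arrays. The samples were 23 arrays from male rats. Per the labels each array holds RNA pooled from 5 animals. The groups were the spontaneously hypertensive rat (SHR, 5 arrays), the Wistar Kyoto rat (WKY, 5 arrays), and Sprague Dawley rats that were controls (4 arrays), fasted for 48 h (5 arrays) or dehydrated for 72 h (4 arrays). The SHR and WKY animals were 10 to 13 weeks old and the Sprague Dawley animals 10 to 12 weeks. Tissue was kept in RNAlater, and RNA was purified on columns and amplified once with a MessageAmp II kit.

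The deposited values are intensity signals on a linear scale, 1 per probe set and array, which the authors made with GCOS 1.2, the Affymetrix array software, per the submitters' processing notes. Its settings are not given in the sources used here. In each array the mean of the values left after removing 2% at each end was 100, which shows that every array had been scaled to the same trimmed mean, so the values were used as deposited, without further normalization. Array medians ran from 39.81 to 44.48. The number of arrays limits the precision, and a signal near the bottom of the range carries background, so that differences at dim probe sets are compressed.

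The table holds 31099 probe sets, of which 57 are Affymetrix controls. Exactly 1 gene symbol was attached to 20832 of them, several symbols to 436 and none to 9780. Current symbols and the order of genes along the chromosomes came from a gene table of the rat assembly GRCr8. No genome position is given for a probe set, since probe sequences were not used here. Groups were assigned from the sample titles, and 0 columns lacked a sample.

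Signals were transformed as log2(signal + 16). Folds are computed from these values, so that they understate ratios at low signal. The control probe sets and the probe sets whose mean over the arrays of a fit lay below the 40th percentile were left out, which kept 18625 probe sets in each fit. SHR and WKY were compared on their 10 arrays. The 13 Sprague Dawley arrays were fitted in 1 model with the contrasts fasted minus control, dehydrated minus control and dehydrated minus fasted. All tests were two-sided limma tests (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend and robust), adjusted by the Benjamini-Hochberg method over the probe sets kept, with a threshold of 0.05. Because each array is a pool, the p-values measure the spread between these samples, and the spread between animals within a pool is not visible. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation, the quality measures and the plots.

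Fixed lists of genes, 21 by function and 13 by cell type, were taken from general knowledge and not from these samples. Each gene counted once, by its probe set with the highest mean. Lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test was run with an estimated correlation, and fry was run as a directional test. The fry test asks whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone.

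The genes named in the text followed a rule. It reads each gene with a single symbol by 1 probe set, the one with the highest mean over the arrays of the fit, so that a gene whose call lies at another of its probe sets falls outside it. For each comparison it takes, among these probe sets, where they pass the threshold and the groups' arrays do not overlap, the 12 largest rises and the 12 largest falls. It adds from each list up to 3 members with the smallest p that pass, and, where fewer than 10 genes pass the first part, the 5 rises and the 5 falls with the smallest p. A fixed set of receptors, enzymes and peptides of this tissue is always given. Genes outside this rule are said to be so where they are named. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined.

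The alternatives were quantile normalization, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, eBayes without trend and robust, array weights, all 23 arrays in 1 model, the replicate number as a block, the log2 ratio of the 3' to the 5' Gapdh control probe sets as a covariate, the mean of all probe sets of a gene, only the 2 groups compared, only control arrays 3 and 4, and each array left out in turn. Control arrays 1 and 2 carry a label protocol text that lacks the closing phrase of the other Sprague Dawley arrays. Further alternatives were chosen after the data were seen and are named as such in the closing part. The pipeline was tested on simulated data, in which 200 probe sets were shifted and every probe set had its own fitted spread. At a true log2 change of 1, it recovered 98.5% of the shifted probe sets for SHR and WKY, 98.5% for fasted and control, 97% for dehydrated and control, and 95.5% for dehydrated and fasted. At a log2 change of 0.5 these shares were 74.6, 67.2, 67.2 and 52.2%. With 200 shifted probe sets many pass, which eases the Benjamini-Hochberg cutoff. The shares therefore overstate recovery where few probe sets pass, as in the Sprague Dawley comparisons.

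RNA quality was read from the control probe sets. The log2 ratio of 3' to 5' Gapdh was 0.208 ± 0.134 in SHR, 0.126 ± 0.074 in WKY, 0.341 ± 0.162 in control, 0.223 ± 0.036 in fasted and 0.409 ± 0.197 in dehydrated arrays (mean ± SD, n = 5, 5, 4, 5 and 4). Over 16 exact two-sided permutation tests of such ratios between groups the smallest p was 0.048, for the 3' to middle ratio of Gapdh in dehydrated against fasted arrays, and its Benjamini-Hochberg value was 0.508. Correlations between arrays of 1 group ran from 0.9747 to 0.9849. The SHR and WKY arrays were submitted apart from the Sprague Dawley arrays, so that strain and submission cannot be separated in any comparison across them, and none is tested in the report.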

Results

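Transcript levels were measured in the rat area postrema, which senses circulating hormones, toxins and plasma composition and projects to medullary autonomic nuclei. The series asks, by its title, how this transcriptome differs in hypertensive, hungry and thirsty rats. It holds 23 arrays, each a pool of 5 animals. SHR, an inbred hypertensive strain, and WKY, its usual normotensive comparison strain, had 5 arrays each. Sprague Dawley rats had 4 control arrays, 5 arrays after 48 h without food and 4 arrays after 72 h of dehydration. Array medians of the scaled signal ran from 39.81 to 44.48, and the highest signal of an array from 6131 to 15483. Signals are given as mean ± SD over the arrays of a group.

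SHR and WKY differed at many genes. Prss35, a secreted serine protease homologue, had a signal of 31.7 ± 5.2 in SHR and 249.5 ± 11.3 in WKY (n = 5 each), which is 5.59-fold lower. Terf2ip, a component of the telomeric shelterin complex, was 2.94-fold lower at 352 ± 41.3 against 1064.3 ± 91.1. Ephx2, the soluble epoxide hydrolase that degrades vasodilator fatty acid epoxides, was 3.35-fold higher at 104.9 ± 5.3 against 21.5 ± 11.9.

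In all, 942 of 18625 probe sets passed the threshold, 405 higher and 537 lower in SHR. They cover 605 distinct named genes, and 291 of the probe sets have no single gene symbol. At least 2-fold differences were found at 56 probe sets, 26 higher and 30 lower. The median size of a passing change was 0.44 (log2), and an unadjusted p below 0.05 was reached by 3208 probe sets (17.22%). The arrays of the strains did not overlap at 1179 probe sets, or 6.33% of those tested, where chance gives 0.79%. When the probe sets of each gene were averaged and tested per gene, 514 of 10476 genes passed. The log2 ratio of 3' to 5' Gapdh was 0.208 in SHR and 0.126 in WKY (exact permutation p = 0.286), and 663 of the 942 calls remained with this ratio as a covariate.

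Among the largest rises, Fry, a microtubule-binding protein, had 405.1 ± 16 in SHR against 140.2 ± 27.5 in WKY (log2 1.45, SE 0.098, adjusted p = 3.44e-08). The zinc finger gene Zfp597 (log2 1.71, SE 0.084, adjusted p = 7.73e-10) and Pxmp4, a peroxisomal membrane protein (log2 1.72, SE 0.105, adjusted p = 7.92e-09), were higher too. RGD1309362, an uncharacterised gene, was near background in WKY with 7.9 ± 5.6 and reached 121.4 ± 21.1 in SHR (log2 2.54, SE 0.146, adjusted p = 4.82e-09). The non-coding gene Abhd11-as1 differed in the same way, 82.1 ± 6.4 against 8.1 ± 4.6 (log2 2.04, SE 0.124, adjusted p = 7.3e-09). Smaller rises of 0.96 to 1.08 (log2) were found for Ccdc3, Creg1, Trim16 and Actr8. For Creg1 another probe set differed by 0.31 and did not pass (adjusted p = 0.171). Prss35 (log2 -2.48, SE 0.086, adjusted p = 5.62e-12) and Terf2ip (log2 -1.56, SE 0.079, adjusted p = 1.02e-09) were among the falls. Clec2d2l2, of the C-type lectin family (log2 -1.86, SE 0.171), Setd1b, a histone methyltransferase (log2 -1.38, SE 0.138), and Mcub, an inhibitory subunit of the mitochondrial calcium uniporter (log2 -1.20, SE 0.075), also fell. Tstd1, Lst1, Ccdc125 and Car14, a membrane-bound carbonic anhydrase, fell by 1.12, 1.07, 1.02 and 1.03 (log2).

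**Figure D1:**
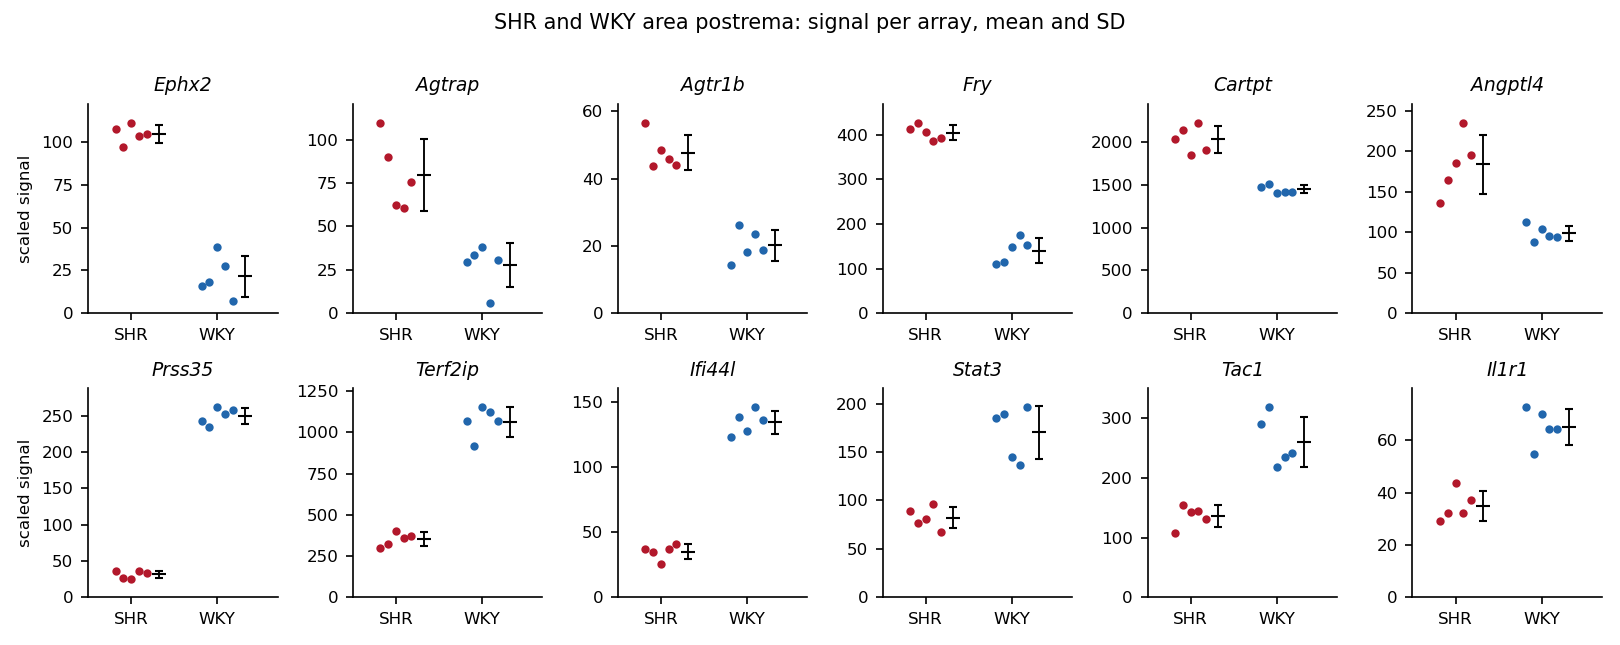
Scaled signal (y axis, linear, from 0) of 12 genes in the 5 SHR and 5 WKY arrays. Each point is 1 array, and the black mark is the mean with 1 SD; Prss35 averages 31.7 in SHR and 249.5 in WKY, and Cartpt 2033.1 and 1447.7.

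Of the 10 measured candidate genes for hypertension, 3 rose and none fell past the threshold, 4 rose adjusted over the list alone, and 6 had a negative difference. The 3 were Ephx2 (log2 1.75, SE 0.169, adjusted p = 6.67e-06), Agtr1b, a rodent angiotensin II type 1 receptor (47.8 ± 5.3 against 20.2 ± 4.6, log2 0.82, SE 0.11, adjusted p = 0.000114), and Gstm1, a glutathione transferase (log2 0.48, adjusted p = 0.00276). The list did not pass against other genes (adjusted p = 0.256), and its median was -0.07 although its mean of 0.25 and its test pointed upwards. Agtrap, which binds the type 1 receptor and promotes its internalization, rose from 27.6 ± 12.5 in WKY to 79.7 ± 20.5 in SHR (log2 1.17, SE 0.223, adjusted p = 0.00669), with a second probe set at 1.87. With a pseudocount of 1 in place of 16, the first probe set of Agtrap did not pass (adjusted p = 0.0572). Agtr1a, the other type 1 receptor gene, differed by -0.08 and did not pass (adjusted p = 0.765). Of the 6 measured genes of the renin-angiotensin system 1 rose and none fell, and adjusted over the list alone 1 rose and 1 fell, with 3 positive and 3 negative differences and no shift of the list that passed (median -0.02, adjusted p = 0.828).

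Among 29 measured neuropeptide and secretory granule genes, 1 rose and 2 fell, or 3 and 2 adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.312). Cartpt, the precursor of an anorexigenic peptide, rose from 1447.7 ± 46.9 to 2033.1 ± 156.2 (log2 0.48, SE 0.056, adjusted p = 2.2e-05). Tac1, the substance P precursor, fell from 260.2 ± 41.6 to 136.1 ± 18 (log2 -0.86, SE 0.103, adjusted p = 4.08e-05). Chgb, a granin, fell by 0.22 (adjusted p = 0.025), and without SHR 1, 3 or 5 or WKY 2, 3 or 4 its adjusted p was 0.0554, 0.0579, 0.0702, 0.0667, 0.0582 and 0.0681. Of 21 measured hormone and peptide receptors 1 rose and 2 fell, or 4 and 2 adjusted over the list alone. The fallen ones were Il1r1, the interleukin-1 receptor (log2 -0.68, SE 0.1, adjusted p = 0.000356), and Npr1, the atrial natriuretic peptide receptor (log2 -0.30, adjusted p = 0.0277). Npr1 lost its call without SHR 3 or 4 (adjusted p = 0.0779 and 0.0737) and without WKY 1, 2, 3 or 4 (0.0608, 0.0581, 0.0539 and 0.0636). Npr1 and Chgb also lost their calls with the 3' to 5' ratio as covariate and with all 23 arrays in 1 model. The calcitonin receptor Calcr, part of the amylin receptor, differed by 0.30 and did not pass (adjusted p = 0.118), although without SHR 3 it did (adjusted p = 0.034). Calcr also passed with the replicate block and, in a fit added after the data were seen, with arrays 1 and 2 against 3 to 5 as a block. Its other probe set differed by -0.15 and did not pass (adjusted p = 0.704).

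Among 12 measured microglia and macrophage markers 3 fell and none rose, or 6 adjusted over the list alone, and 11 had a negative difference (median -0.26, adjusted p = 6.31e-05 at the preset correlation). The list did not pass with an estimated correlation (adjusted p = 0.393). The fallen markers were the complement genes C1qa (log2 -0.35, adjusted p = 0.00778) and C1qc (log2 -0.41, adjusted p = 0.0321) and the calcium-binding protein Aif1 (log2 -0.39, adjusted p = 0.027), whose other probe set differed by -0.08. With 1 array left out, C1qc passed only without SHR 1 or WKY 3 or 4. The other omissions, of SHR 2, 3, 4 and 5 and WKY 1, 2 and 5, gave adjusted p = 0.0601, 0.0889, 0.0725, 0.0538, 0.0901, 0.0831 and 0.077. Aif1 lost its call without SHR 3, 4 or 5 or WKY 1, 2 or 5 (adjusted p = 0.0567, 0.0515, 0.0654, 0.0673, 0.0601 and 0.0778). Both C1qc and Aif1 also lost their calls with the 3' to 5' ratio as covariate, without a filter, and with eBayes without trend and robust.

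Of 11 measured inflammation genes 4 fell and none rose, and the same numbers held adjusted over the list alone (median -0.13, adjusted p = 0.0196, and 0.486 as the adjusted p with an estimated correlation). They included Stat3, the transcription factor of interleukin-6 signalling (82.3 in SHR, 170.4 in WKY, log2 -0.92, SE 0.105, adjusted p = 2.06e-05), Il1r1, and Ptgs2, the inducible cyclooxygenase (log2 -0.58, adjusted p = 0.0184). The other probe set of Stat3 differed by 0.04 (adjusted p = 0.945). Ptgs2 lost its call without SHR 3 or 5 (adjusted p = 0.0509 and 0.0515) or WKY 1 or 2 (0.057 and 0.0543), and the list lost its call without WKY 1 (adjusted p = 0.0913). With the 3' to 5' ratio as covariate Ptgs2 did not pass either.

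Of 27 measured genes of the interferon response and antigen presentation 4 fell and 1 rose, with the same numbers adjusted over the list alone (median -0.05, adjusted p = 0.0248, and adjusted p = 0.832 with an estimated correlation). The list passed with all arrays but not without SHR 1 (adjusted p = 0.0554), SHR 3 (0.361) or WKY 1, 2, 3, 4 or 5 (0.0742, 0.175, 0.079, 0.13 and 0.199). The interferon-induced gene Ifi44 fell by 0.80 (adjusted p = 5.97e-05), and Ifi44l, outside the list, by 1.56, from 134.1 to 35 (adjusted p = 6.4e-09). The class II gene RT1-Bb fell by 1.38 (adjusted p = 1.92e-06). The class I probe sets of RT1-CE16 (log2 1.95) and RT1-CE5 (log2 -1.02) can bind transcripts of near-identical family members, so that the gene behind each is uncertain.

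Genes of lipid handling moved in both directions. Of 25 measured genes of fatty acid oxidation and ketone metabolism 5 rose and none fell, or 6 and 1 adjusted over the list alone, while the list did not pass against other genes (median 0.03, adjusted p = 0.0748). They included Angptl4, an inhibitor of lipoprotein lipase (183.5 in SHR, 98.4 in WKY, log2 0.79, SE 0.109, adjusted p = 0.000177), Acot1, an acyl-CoA thioesterase (log2 0.63, adjusted p = 0.00019), and Ech1, an auxiliary enzyme of beta-oxidation (log2 0.29, adjusted p = 0.00255). Of 12 genes of fatty acid synthesis 2 fell and 1 rose, or 7 and 1 adjusted over the list alone (median -0.18, adjusted p = 0.0196, and adjusted p = 0.393 with an estimated correlation). Me1, which supplies NADPH, fell from 1059.5 to 675.9 (log2 -0.64, SE 0.071, adjusted p = 1.33e-05), Scd, the stearoyl-CoA desaturase, fell by 0.52 (adjusted p = 0.0308), and the elongase Elovl6 rose by 0.66 (adjusted p = 0.000367) with a second probe set at 0.28 that did not pass. Scd lost its call without SHR 2 or 4 (adjusted p = 0.0686 and 0.0849) or WKY 3 or 4 (0.0888 and 0.0796), and the synthesis list lost its call without WKY 3 (0.0598) or WKY 5 (0.0555). With the 3' to 5' ratio as covariate, without a filter or with all 23 arrays in 1 model Scd did not pass either.

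All 9 measured markers of fibroblasts and meninges had negative differences, 3 of them past the threshold and 3 adjusted over the list alone (median -0.27, adjusted p = 6.31e-05, and adjusted p = 0.393 with an estimated correlation). The type I collagen gene Col1a2 fell from 1948.8 to 1227.5 (log2 -0.67, SE 0.107, adjusted p = 0.00153), and the growth factor Igf2 and the matrix protein Fmod fell by 0.53 and 0.51 (adjusted p = 0.00462 and 0.000805). The mean of these markers, centred over the arrays, was -0.16 ± 0.1 in SHR and 0.16 ± 0.23 in WKY, and that of the microglia markers -0.12 ± 0.14 and 0.12 ± 0.05. No other cell type list with at least 3 measured members passed. Single markers of other lists did: Enpp2, the lysophospholipase autotaxin, rose from 660.4 to 1112.9 (log2 0.74, SE 0.054, adjusted p = 9.14e-08), Prph, the intermediate filament peripherin, rose by 0.72 (adjusted p = 0.000102), and the calcium buffer Calb1 rose by 0.44 (adjusted p = 0.00392). With all 23 arrays in 1 model Enpp2 (adjusted p = 0.309) and Prph (0.256) did not pass.

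Further list members that passed were Gch1, the first enzyme of tetrahydrobiopterin synthesis (log2 0.40), the metallothionein Mt2A (log2 0.36), Psat1 of serine synthesis (log2 0.33) and the water and glycerol channel Aqp9 (log2 0.30), all higher. Gch1 did not pass when its probe sets were averaged (adjusted p = 0.244), nor Aqp9 with all 23 arrays in 1 model (0.0689). Mcm2, a replication licensing factor, fell by 0.52, the phosphatase Dusp1 by 0.46 and Sdha, a subunit of succinate dehydrogenase, by 0.33. Receptors and enzymes for which this organ is known did not pass: Glp1r, the receptor of glucagon-like peptide 1, differed by 0.02 (adjusted p = 0.965), the amylin receptor component Ramp3 by 0.18 (0.399), the calcium-sensing receptor Casr by 0.19 (0.319) and the vasopressin receptor Avpr1a by 0.21 (0.349). Values for the adiponectin receptors Adipor1 and Adipor2 were -0.06 (0.684) and 0.08 (0.771). The catecholamine enzymes Th and Dbh differed by -0.01 (0.98) and -0.10 (0.724), and the activity-dependent gene Fos by 0.04 (0.888). Lepr, the leptin receptor, lay below the filter in every comparison.

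Few probe sets passed the threshold after fasting for 48 h. Cdh1, the epithelial adhesion protein E-cadherin, rose from 48.9 ± 4.2 in 4 control arrays to 95.2 ± 7 in 5 fasted arrays (1.71-fold, log2 0.78, SE 0.093, adjusted p = 0.000807). Cdo1, cysteine dioxygenase, which starts cysteine breakdown to taurine, fell from 1020.5 ± 170.6 to 602 ± 71.2 (log2 -0.74, SE 0.118, adjusted p = 0.0306), and Olfml3, a secreted matrix glycoprotein, from 553.3 ± 61.2 to 323.7 ± 63.4 (log2 -0.76, SE 0.122, adjusted p = 0.0306). A probe set of Klhl24, an adaptor of ubiquitin ligases, rose from 74.2 ± 7.2 to 134.8 ± 14.7 (log2 0.74, adjusted p = 0.00241), while its other 2 probe sets, 1 of them with the higher mean, differed by 0.08 and -0.05. Klhl24 falls outside the naming rule, which reads a gene by its probe set with the highest mean, and was named after its values were seen.

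These were the only 4 of 18625 probe sets past the threshold, and 1340 (7.19%) had an unadjusted p below 0.05. Groups without overlap were found at 2.32% of probe sets, where chance gives 1.59%. The count was 2 without control 2, fasted 3 or fasted 4, and 0 with control arrays 3 and 4 alone, where Cdh1 no longer passed. Cdh1 also lost its call with all 23 arrays in 1 model. Cdo1 lost its call without control 1, 2 or 4 (adjusted p = 0.128, 0.15 and 0.173) or fasted 1, 2, 3 or 4 (0.0572, 0.0701, 0.0831 and 0.126), and Olfml3 without control 1, 2 or 4 (0.144, 0.15 and 0.173) or fasted 1, 3, 4 or 5 (0.0572, 0.16, 0.11 and 0.0876). Both also lost their calls with the 3' to 5' ratio as covariate, without a filter, and with eBayes without trend and robust.

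Among the genes with the next smallest p, none of which passed, were Efemp1 (log2 0.57, adjusted p = 0.192), Mettl7a (0.46, 0.105), Pals2 (0.36, 0.229) and Tcp11l2 (0.36, 0.226) with positive values, and Lgals1, a galectin (-0.55, 0.057), Tnfrsf1a, a tumour necrosis factor receptor (-0.46, 0.145), and Acsbg1, an acyl-CoA synthetase of glia and steroid-producing cells (-0.42, 0.105), with negative values. Lgals1 depended on the settings: it passed without control 3 (adjusted p = 0.0173) or fasted 2 (0.0332), with a pseudocount of 64, with the filter at the 60th percentile, with array weights, with all 23 arrays in 1 model, with only the 2 groups compared and, in a fit added after the data were seen, with the choroid plexus marker mean as covariate (0.0173 to 0.477 over all alternatives). Acsbg1 passed without fasted 2 (0.0206) and Efemp1 without control 4 (0.0296). The genes of feeding signals that are always given did not pass. Calcr differed by -0.13, Glp1r by 0.10, Ramp3 by 0.04, Cartpt by -0.15, Th by -0.15, Dbh by 0.02, Fos by 0.07, Agtr1a by -0.12, Casr by -0.05, Avpr1a by -0.08, Adipor1 by 0.02 and Adipor2 by 0.05.

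At the preset correlation, gene lists shifted by small amounts without single members passing over all probe sets. Of 29 measured oxidative phosphorylation genes 27 had negative values (median -0.13, adjusted p = 4.17e-08, and adjusted p = 0.496 with an estimated correlation), and none passed adjusted over the list alone. Of 19 cholesterol synthesis genes 16 were negative (median -0.15, adjusted p = 0.000436, and 0.496 as the adjusted p with an estimated correlation), with 1 fall adjusted over the list alone. Of 11 fatty acid synthesis genes 10 were negative (median -0.14, adjusted p = 0.000532, and adjusted p = 0.234 with an estimated correlation), with 2 falls adjusted over the list alone. Interferon and antigen presentation genes were negative at 24 of 28 (median -0.16, adjusted p = 0.00441, and adjusted p = 0.53 with an estimated correlation), and inflammation genes at 7 of 10 (median -0.18, adjusted p = 0.0488, and adjusted p = 0.255 with an estimated correlation). Insulin and FOXO response genes, which FOXO factors induce when insulin is low or which act in insulin signalling, were positive at 13 of 18 (median 0.08, adjusted p = 0.0338, and adjusted p = 0.234 with an estimated correlation). None of these 3 lists had a member past the threshold adjusted over the list alone. Fibroblast and meninges markers were negative at 8 of 10 (median -0.21, adjusted p = 0.00441, and adjusted p = 0.306 with an estimated correlation), 2 of them past the threshold adjusted over the list alone. Their centred mean was 0.19 ± 0.15 in control and -0.09 ± 0.2 in fasted arrays.

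Of these lists, inflammation lost its call without control 1 (adjusted p = 0.152), control 4 (0.0746) or fasted 2, 3 or 4 (0.0591, 0.0703 and 0.319), the insulin and FOXO list without control 2, 3 or 4 (0.0983, 0.0748 and 0.0553) or fasted 3 (0.0703), and the interferon list without control 4 (0.0553) or fasted 4 (0.0509). The log2 ratio of 3' to 5' Gapdh was 0.341 ± 0.162 in control and 0.223 ± 0.036 in fasted arrays.

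After dehydration for 72 h Bdnf, brain-derived neurotrophic factor, rose 2.25-fold, from 102 ± 18.3 in 4 control arrays to 247.2 ± 16.2 in 4 dehydrated arrays (log2 1.17, SE 0.117, adjusted p = 4.69e-05). Vgf, a granin-like peptide precursor that neurotrophins induce, rose from 343.6 ± 49.5 to 512.7 ± 27.9 (log2 0.57, SE 0.094, adjusted p = 0.0148), and Nmu, neuromedin U, a peptide acting on feeding and stress responses, from 104.7 ± 21.2 to 171.5 ± 14 (log2 0.65, SE 0.114, adjusted p = 0.0164). Cdh1 rose to 87.5 ± 3.8 (log2 0.68, SE 0.098, adjusted p = 0.00515). The largest falls were those of Wfdc1, a secreted protease inhibitor (796.3 ± 74.1 to 395.3 ± 77.1, log2 -0.99, SE 0.152, adjusted p = 0.0148), and Olfml3 (to 287.6 ± 43.4, log2 -0.91, SE 0.129, adjusted p = 0.00515).

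In all, 31 of 18625 probe sets passed, 10 higher and 21 lower, and 2176 (11.68%) had an unadjusted p below 0.05. Of these 31, 30 had the same sign in fasted arrays, which the shared control arrays favour, and 3 passed there too. Only 1, that of Bdnf, differed past the threshold between dehydrated and fasted arrays, so that the others are not shown to be particular to dehydration. Groups did not overlap at 6.68% of probe sets, where chance gives 2.86%. The count rests on few arrays. It was 15, 12 and 9 without control 1, 2 and 4, 9 and 12 without dehydrated 1 and 2, and 2 with control arrays 3 and 4 alone or, in a fit added after the data were seen, without dehydrated 1 and 2 together. Rises and falls were even, 6 and 6, without control 2, nearly so, 7 and 8, without control 1, and 34 and 40 with all 23 arrays in 1 model. Only Bdnf passed in every alternative, among the 28 named genes. Its second probe set, at the same gene, differed by -0.14 and did not pass (adjusted p = 0.759). That probe set was dim, with a mean signal of 31 in dehydrated arrays.

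Further rises passed at Atl1, an endoplasmic reticulum shaping GTPase (log2 0.45, with another probe set at -0.20 that did not pass), and Wsb1, an ubiquitin ligase subunit (log2 0.43). Outside the naming rule, Id4, an inhibitor of differentiation (log2 0.50), and Elavl2, a neuronal RNA-binding protein (log2 0.43), rose, each at 1 of several probe sets. Cdo1 fell to 612 ± 97.6 (log2 -0.72, SE 0.124, adjusted p = 0.0201), Cbs, cystathionine beta-synthase, by 0.42 (adjusted p = 0.0454), Inmt, a methyltransferase of indoles and thioethers, by 0.76 (adjusted p = 0.012), and Tcn2, the vitamin B12 carrier transcobalamin, from 1272 ± 119.2 to 767.9 ± 120.1 (log2 -0.72, adjusted p = 0.016). Glial Acsbg1 fell from 910.8 ± 18.3 to 597.8 ± 29.5 (log2 -0.60, SE 0.085, adjusted p = 0.00515). The remaining falls of genes within the rule that belong to none of the lists were Pola2 (log2 -0.72), Smpdl3b (log2 -0.68), Ptpru (log2 -0.62) and Slc24a4 (log2 -0.57). Tspo, a mitochondrial outer membrane protein, fell by 0.54, the actin-binding protein Synpo by 0.51 and complement C3 by 0.44. Tspo, Synpo, C3 and Cbs were named after their values were seen.

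Most of these calls needed nearly all arrays. Bdnf, Cdh1, Olfml3, Acsbg1 and Hspb1 passed whichever single array was left out. Inmt lost its call without control 2 (adjusted p = 0.0564), Vgf without control 4 or dehydrated 1 (0.0612 and 0.0529) and Nmu without control 1 or 4 or dehydrated 1 or 2 (0.0582 to 0.109). Wfdc1 and Acadvl lost theirs without control 1, 2 or 4 or dehydrated 1 or 2 (0.0529 to 0.0582 and 0.0534 to 0.0912), as did Ldha (0.0747 to 0.114) and Tspo (0.0837 to 0.114). Smpdl3b lost its call without control 1 or 2 or dehydrated 1 or 2 (0.0564 to 0.0632), Tcn2 without control 1, 2 or 4 or dehydrated 2 (0.0538 to 0.0873), C3 without control 4 or dehydrated 1 or 2 (0.0529 to 0.0912) and Id4 without control 2 or 4 or dehydrated 2 or 3 (0.0564 to 0.114). For Cdo1 and Synpo the arrays were control 1, 2 and 4 and dehydrated 1 and 3 (0.0567 to 0.114 and 0.0721 to 0.109), for Ptpru control 2 and 4 and dehydrated 1, 2 and 3 (0.0837 to 0.149), and for Cbs control 1, 2 and 4 and dehydrated 1, 2 and 3 (0.0978 to 0.203). Wsb1 lost its call without any array but control 1 and dehydrated 4 (0.0547 to 0.141), Serpinh1 without any but control 2 and dehydrated 4 (0.0792 to 0.197), Slc24a4 without any but control 4 and dehydrated 3 (0.0561 to 0.113), and Mas1, Nqo1 and Elavl2 without any but dehydrated 4 (0.0613 to 0.158, 0.0848 to 0.159 and 0.0663 to 0.167). Atl1 kept its call only without dehydrated 2 and Pola2 only without dehydrated 3, with adjusted p = 0.0521 to 0.115 and 0.0647 to 0.158 otherwise.

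**Figure D2:**
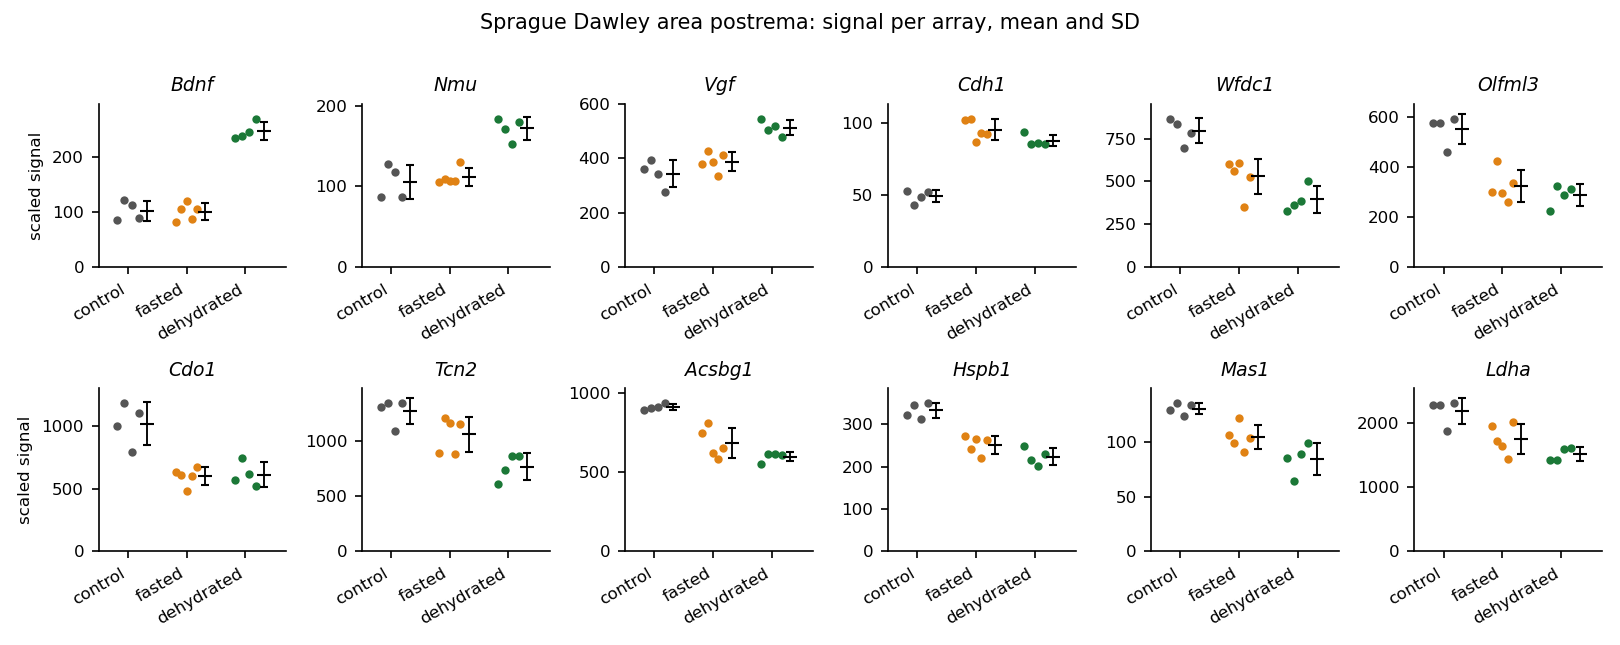
Scaled signal (y axis, linear, from 0) of 12 genes in the 4 control, 5 fasted and 4 dehydrated Sprague Dawley arrays. Each point is 1 array, and the black mark is the mean with 1 SD; Bdnf averages 102 in control, 100.4 in fasted and 247.2 in dehydrated arrays.

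Of 30 measured neuropeptide and secretory granule genes 3 rose and none fell, or 8 and 2 adjusted over the list alone, and 22 were positive (median 0.14, adjusted p = 6.29e-05, and adjusted p = 0.368 with an estimated correlation). The mean of 0.31 was pulled up by Avp and Oxt, which were high in dehydrated 1 and 2 and did not pass (adjusted p = 0.258 and 0.313). Without these 2 genes, a choice made after the data were seen, the list's adjusted p was 0.00112. Neuron markers were positive at 9 of 12, with none past the threshold and 1 rise adjusted over the list alone (median 0.13, adjusted p = 0.0121, and adjusted p = 0.368 with an estimated correlation). All 4 measured markers of cholinergic motor neurons were positive, none past the threshold and 1 adjusted over the list alone (median 0.40, adjusted p = 0.0112, and adjusted p = 0.368 with an estimated correlation). The motor neuron list lost its call without dehydrated 1 (adjusted p = 0.0977), and the neuron list without dehydrated 1 (0.0958) or 4 (0.0736). The centred mean of the cholinergic markers was -0.17 ± 0.18 in control and 0.21 ± 0.38 in dehydrated arrays, and that of the neuron markers -0.05 ± 0.02 and 0.05 ± 0.1.

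**Figure D3:**
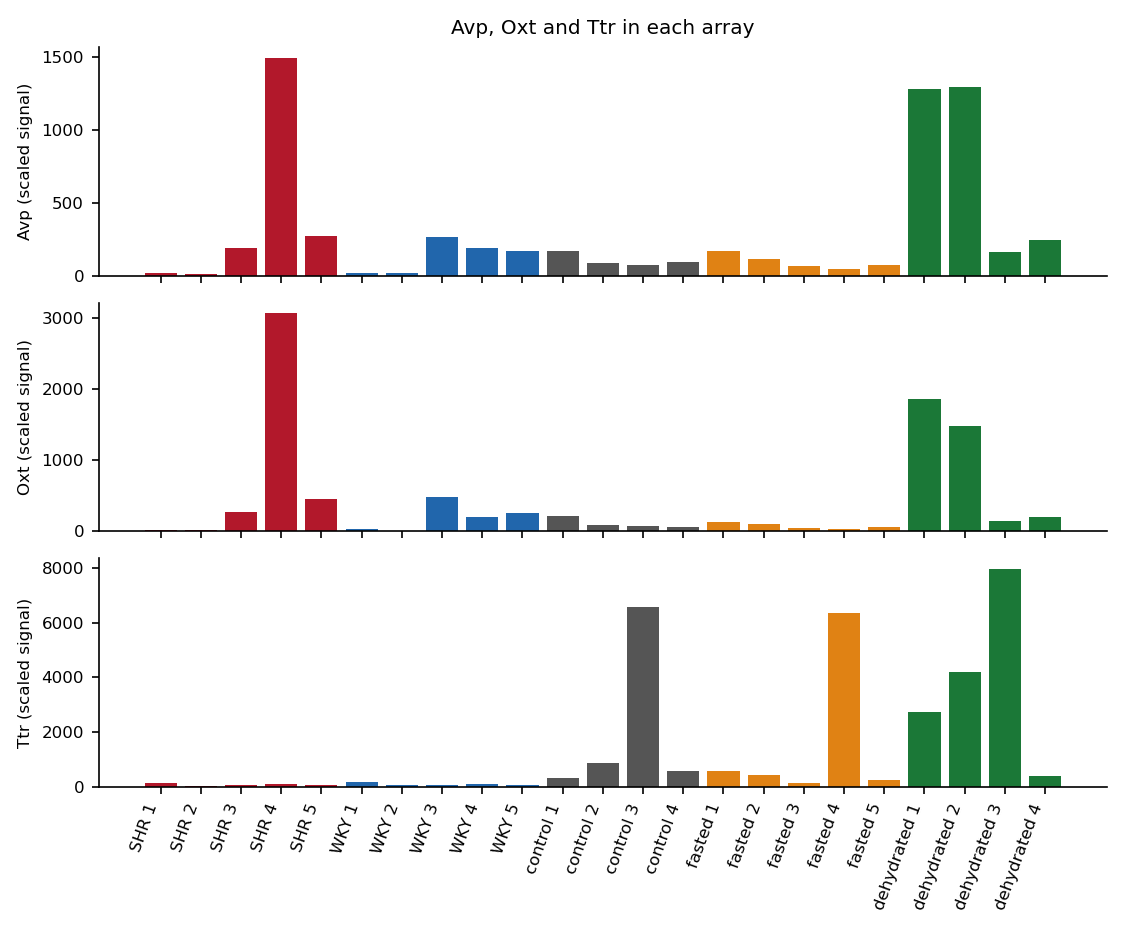
Scaled signal (y axes, linear, from 0) of Avp, Oxt and Ttr in each of the 23 arrays, with 1 bar per array coloured by group. Avp and Oxt are highest in SHR 4 and dehydrated 1 and 2, and Ttr in dehydrated 3, control 3 and fasted 4, with 7953.2, 6558.6 and 6342.6.

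All 25 measured genes of oxidative stress and glutathione were negative, 1 past the threshold and 6 adjusted over the list alone (median -0.14, adjusted p = 6.23e-05, and adjusted p = 0.368 with an estimated correlation). The 1 was Nqo1, a quinone reductase (285 to 214.1, log2 -0.39, adjusted p = 0.0454). Of 24 genes of fatty acid oxidation and ketone metabolism 21 were negative, 1 of them past the threshold and 5 adjusted over the list alone (median -0.14, adjusted p = 0.00179, and adjusted p = 0.368 with an estimated correlation). It was Acadvl, the very long chain acyl-CoA dehydrogenase (395.9 to 280.9, log2 -0.47, adjusted p = 0.016). Oxidative phosphorylation genes were negative at 26 of 29, with none past the threshold on either adjustment (median -0.10, adjusted p = 0.000481, and adjusted p = 0.599 with an estimated correlation). Ldha, lactate dehydrogenase A, fell from 2182.7 to 1510.4 (log2 -0.52, SE 0.095, adjusted p = 0.0205), the only member of 16 hypoxia and glycolysis genes to do so, over all probe sets or adjusted over the list alone.

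Of 15 chaperones 2 fell, or 2 adjusted over the list alone. They were the small heat shock protein Hspb1 (332.6 ± 18.3 to 223.8 ± 20.3, log2 -0.54, SE 0.085, adjusted p = 0.00821) and the collagen chaperone Serpinh1 (log2 -0.53, adjusted p = 0.0435), and the list did not pass (adjusted p = 0.0647). Fibroblast and meninges markers were negative at 8 of 10, none past the threshold and 2 adjusted over the list alone (median -0.29, adjusted p = 0.0121, and adjusted p = 0.368 with an estimated correlation), and the list lost its call without control 2 (adjusted p = 0.0707) or dehydrated 4 (0.115). Their centred mean was 0.19 ± 0.15 in control and -0.08 ± 0.3 in dehydrated arrays, and that of the choroid plexus markers -0.07 ± 0.79 and 0.37 ± 0.79. The log2 ratio of 3' to 5' Gapdh was 0.341 in control and 0.409 in dehydrated arrays, highest in control 2 (0.571) and dehydrated 2 (0.68). Without both of these arrays, a choice made after the data were seen, 6 probe sets passed.

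Of 7 renin-angiotensin genes 1 fell, or 1 adjusted over the list alone: Mas1, the receptor of angiotensin (1-7), from 130.7 ± 5.4 to 84.6 ± 14.6 (log2 -0.56, SE 0.11, adjusted p = 0.0402). None of 16 osmotic stress genes, 9 immediate early genes or 15 glucocorticoid response genes passed over all probe sets, and adjusted over the list alone 0, 0 and 2 fell. Fos differed by 0.34 (adjusted p = 0.375), Avpr1a by 0.22 (0.539), Agtr1a by -0.13 (0.664) and Cartpt by -0.44 (0.214), with signals of 1789.4 for Cartpt in dehydrated and 2422.1 in control arrays. Th and Dbh differed by -0.18 (0.481) and -0.34 (0.248), Glp1r by 0.15 (0.775) and Calcr by 0.01 (0.98). Casr at 0.07, Ramp3 at -0.02, Adipor1 at -0.09 and Adipor2 at -0.04 did not pass either.

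**Figure D4:**
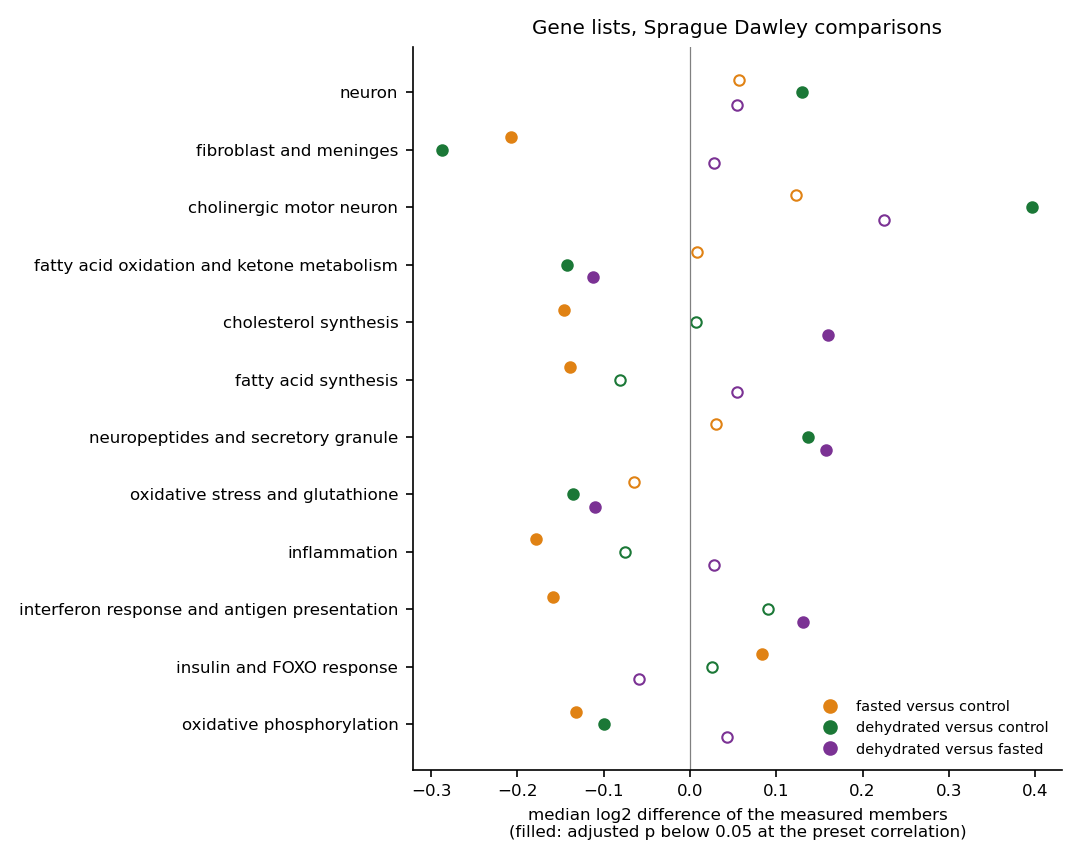
Median log2 difference of the measured members (x axis) for the 12 gene lists (y axis) that passed at the preset correlation in at least 1 Sprague Dawley comparison, with 1 point per list and comparison; filled points passed. The fibroblast and meninges median is -0.21 after fasting and -0.29 after dehydration, and the cholesterol synthesis median is -0.15 after fasting and 0.16 between dehydrated and fasted arrays.

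Dehydrated and fasted arrays were compared directly, which needs no control array. Bdnf was 2.27-fold higher after dehydration than after fasting (247.2 ± 16.2 in 4 arrays against 100.4 ± 15.7 in 5, log2 1.19, SE 0.111, adjusted p = 1.44e-05), and its second probe set differed by -0.18 (adjusted p = 0.714). Averaging both probe sets ended the call (adjusted p = 0.0743). The second one was dim, with mean signals of 31 in dehydrated and 37.3 in fasted arrays, where array medians were 39.81 to 44.48. The Klhl24 probe set that rose after fasting was lower after dehydration, 72.3 ± 6.9 against 134.8 ± 14.7 (log2 -0.77, SE 0.099, adjusted p = 0.00128), with the other probe sets of the gene at 0.10 and -0.02. Sh3bgrl1, a small thioredoxin-fold protein, was higher at 548.3 against 394.9 (log2 0.45, adjusted p = 0.0187), and Pbxip1, an interaction partner of PBX factors, lower at 145.7 against 221.8 (log2 -0.56, adjusted p = 0.00834).

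In all, 6 probe sets passed, 2 higher and 4 lower, of which 2 lower ones, at -0.67 and -0.44, have no single gene symbol, and 1862 (10%) had an unadjusted p below 0.05. Groups did not overlap at 3.23% of probe sets, where chance gives 1.59%. The count was 2 without dehydrated 1 and 10 without fasted 1. Pbxip1 lost its call without dehydrated 1 (adjusted p = 0.053), and Sh3bgrl1 without dehydrated 1, 2 or 3 (0.075, 0.0849 and 0.134) or fasted 3, 4 or 5 (0.059, 0.0528 and 0.0676). Both also lost their calls with the 3' to 5' ratio as covariate, and Sh3bgrl1 with the choroid plexus marker mean as covariate, a choice made after the data were seen. The log2 ratio of 3' to 5' Gapdh was 0.409 ± 0.197 in dehydrated and 0.223 ± 0.036 in fasted arrays (exact permutation p = 0.063, Benjamini-Hochberg 0.508), and the ratio of 3' to middle 0.478 ± 0.052 and 0.387 ± 0.071 (exact permutation p = 0.048, Benjamini-Hochberg 0.508). The centred mean of the choroid plexus markers was 0.37 ± 0.79 and -0.24 ± 0.97, and that list did not pass (median 0.47, adjusted p = 0.246).

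Nmu differed by 0.56 and did not pass (adjusted p = 0.1), nor did Agpat5 (0.40, 0.129) and the oxygen-binding protein Ngb (0.36, 0.197). Fibcd1 at -0.82 (adjusted p = 0.0741), Txnip, a thioredoxin inhibitor, at -0.57 (0.118), Nbl1 at -0.39 (0.118) and C3 at -0.37 (0.107) did not pass. Fibcd1 passed without fasted 5 (adjusted p = 0.0431) and Txnip without fasted 1 (0.0369) or with array weights (0.0344). Nmu passed with only the 2 groups compared (0.0399, and 0.0399 to 0.677 over the alternatives) and Ngb with the choroid plexus marker mean as covariate, a fit added after the data were seen (0.0407, and 0.0407 to 0.677). The differences of Fos at 0.27, Avpr1a at 0.29, Cartpt at -0.29 and Dbh at -0.36 did not pass either.

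At the preset correlation, 5 lists differed between dehydrated and fasted arrays. Cholesterol synthesis genes were positive at 17 of 19 (median 0.16, adjusted p = 2.93e-05) with 1 rise adjusted over the list alone, and interferon and antigen presentation genes at 20 of 28 (median 0.13, adjusted p = 2.93e-05) with 4 rises adjusted over the list alone. Neuropeptide and granule genes were positive at 20 of 30 (median 0.16, adjusted p = 2.93e-05), 1 past the threshold, which was Bdnf, and 7 adjusted over the list alone, and the list's adjusted p without Avp and Oxt was 0.000895. Fatty acid oxidation genes were negative at 21 of 24 (median -0.11, adjusted p = 0.000378), with 3 falls adjusted over the list alone, and oxidative stress genes at 20 of 25 (median -0.11, adjusted p = 0.00134), with 3 falls and 1 rise. For all 5 lists the adjusted p was 0.391 with an estimated correlation. In the 4 comparisons no list that passed at the preset correlation passed with an estimated correlation.

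Cdh1 was higher and Cdo1 and Olfml3 were lower both after fasting and after dehydration. Both comparisons use the same 4 control arrays, which alone makes their fold changes covary, so that these 3 probe sets alone do not show an overlap of the responses. In 100 simulations of unchanged groups measured against shared controls the number passing in both was 0 for rises and 0.01 on average, at most 1, for falls, but these simulations leave both groups unchanged, so that they do not show what shared controls give when 1 group has changed. The covariance over all probe sets was 0.0117, against a mean of 0.00861 (0.00817 to 0.00917) in the same simulations. The simulations gave every group the same fitted spread. Control arrays correlated less with each other (median r 0.976) than fasted (0.9805) or dehydrated arrays (0.9799), so that the simulated covariance may be too low. The correlation across genes, which are not independent replicates, was 0.506 against 0.527 in the simulations, and 67.67% of probe sets had the same sign against 67.68%. With the controls split, arrays 1 and 2 for fasting and 3 and 4 for dehydration, the covariance was 0.00283, and with the reverse assignment 0.00108.

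**Figure D5:**
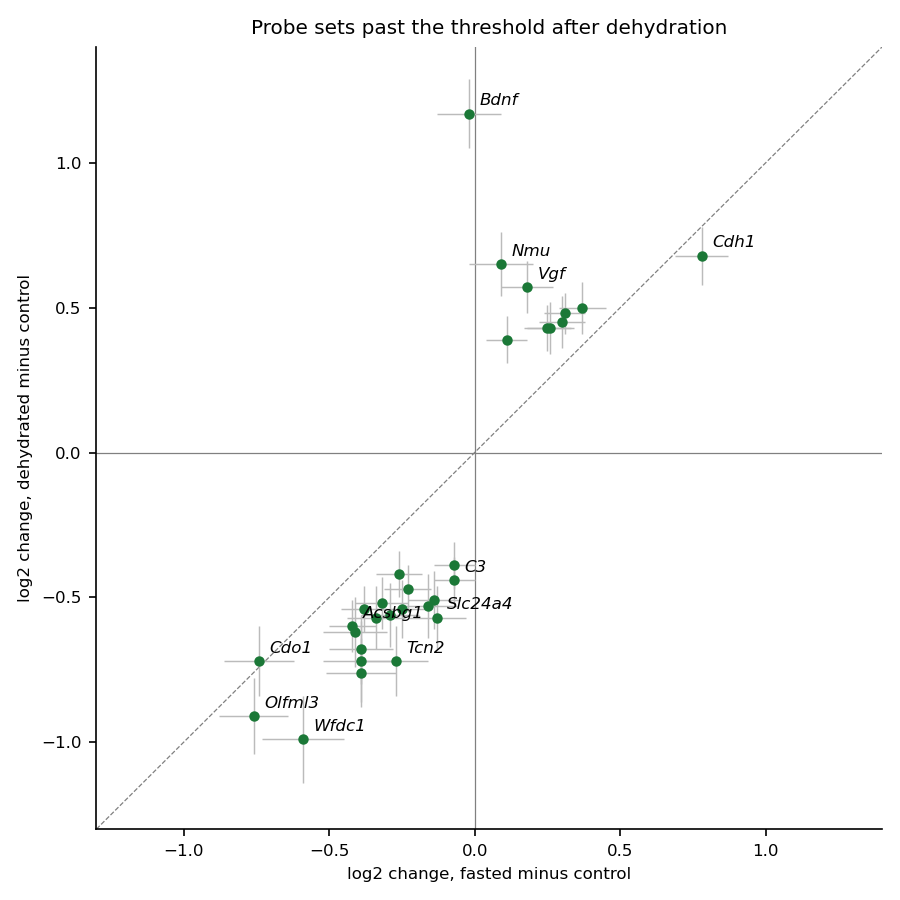
Log2 change after fasting (x axis) and after dehydration (y axis), each against the same control arrays, for the 31 probe sets past the threshold after dehydration. Bars are 1 SE of the fit and the dashed line marks equal change; Bdnf lies at 1.17 after dehydration and -0.02 after fasting.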

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

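The test of RNA integrity as a cause of the strain pattern, which uses a fit planned as an alternative, the test of Avp against choroid plexus markers, and 4 of the 6 divisions of the control arrays were chosen only after the results were seen, as was the requirement that the upper 95% bound of a correlation lie under 0.6 before it counts against an explanation.

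SHR and WKY differed at 942 probe sets. Sequence variants under single probe sets are argued against as the whole cause only for the 220 of 605 passing genes with other probe sets. Of these 321 other probe sets 239 (74.5%, exact 95% interval 69.3 to 79.1) differed in the same direction, against 61.1% for genes that did not pass. Their median difference in the direction of the passing probe set was only 0.12. The passing probe sets had a median size of 0.43, but this was taken over all 605 genes, each at its probe set with the smallest p. The 2 medians thus cover different genes. Of the other probe sets 46 passed, 44 in the same direction. RNA integrity as the whole cause is argued against by the 663 calls that remained with the 3' to 5' ratio as covariate. A chance division of the arrays is argued against by the splits, of which 100 of 126 possible ones were run. Of these 1, the real one, gave as many calls, and the highest other gave 14 (SHR 1 and 2 with WKY 1, 2 and 4 against the rest). Inherited blocks of neighbouring genes, the biological explanation that strains offer, may account for part of it. Of the passing genes 21.4% lay next to another passing gene, where 10000 random placements gave 11.1% (7.8 to 14.6, at most 18.2). Next to here means next among the 10470 tested genes that could be placed, whatever the distance and the untested genes between. Only 40 of 69 adjacent pairs shared a direction (exact binomial p = 0.228), and 7 pairs had the same name stem. Sequence variants under probes would lie in such blocks too, so that this share cannot part them from differences in expression. Hypertension itself, other strain differences and, for genes seen at their only probe set or at 1 of several, sequence variants stay open, since 1 pair of strains cannot part them.

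Cdo1 and Olfml3 were lower than in the same control arrays in both fasted and dehydrated arrays, and the falls after dehydration were weighed as a set. Choroid plexus content of the dissections is argued against as the whole cause, because with the choroid plexus marker mean as covariate 96.9% of the median fall remained (-0.57 before and -0.55 after, SE 0.11), all 21 probe sets stayed lower and 13 still passed, even though the fallen genes followed these markers within groups (r = -0.69, 95% interval -0.91 to -0.15, permutation p = 0.01, Benjamini-Hochberg 0.025 over 5 relations, rho = -0.48 with p = 0.0963 and Benjamini-Hochberg 0.241), a relation that rests on fasted 4 and control 3 (r = -0.12 without them). Less fibroblast and meningeal tissue stays open: the residual correlation of its markers with the fallen genes was 0 (permutation p = 0.995, Benjamini-Hochberg 0.995, rho = 0.03 with p = 0.92, -0.27 without dehydrated 3 and control 2), which meets the bound of 0.3 set for excluding it, but 13 arrays leave an interval of -0.6 to 0.6. The shared control arrays stay open too, since the covariance exceeded its simulated mean by 0.00313 and every simulated value, as did the planned control divisions, yet over all 6 divisions it ran from -0.00149 to 0.00373 (median 0.00253), and the simulated range (-0.000674 to 0.000786) treats probe sets as independent and so is too narrow, while the correlation of the changes (0.5055) lay below its simulated range of 0.5093 to 0.5437. The simulations also gave all groups the same fitted spread, which may understate what the control arrays share. A common effect of water and food deprivation, which the design offers as the biological explanation, was not separated from these explanations.

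Avp and Oxt were high in dehydrated 1 and 2 (Avp 1286.6 and 1298.9, Oxt 1863.5 and 1473.7) and in SHR 4 (1497.3 and 3062.4), against 159.1 and 244.5 for Avp in dehydrated 3 and 4 and 75.2 to 168.4 in control arrays, and both were near background in arrays 1 and 2 of SHR and WKY (Avp 16.8, 9.2, 16.2 and 17.3, Oxt 18.5, 18.7, 26.4 and 9.3), while Avp was 192.1 and 270.9 in SHR 3 and 5 and 266.1, 186.9 and 170.8 in WKY 3, 4 and 5. The peptides rose and fell together over the 13 Sprague Dawley arrays within groups (r = 0.98, permutation p = 1e-05, the smallest the 100000 resamplings can give, rho = 0.94, and r = 0.96 without dehydrated 1 and 3). Choroid plexus content is argued against, since the residual correlation of Avp with its markers was -0.26 with an upper 95% bound of 0.41 (permutation p = 0.398, Benjamini-Hochberg 0.647, rho = -0.02 with p = 0.949, r = -0.05 without fasted 4 and control 3). An effect of dehydration in the dehydrated arrays was not shown, since the difference from control did not pass (adjusted p = 0.258 for Avp), and it cannot apply to SHR 4. The neuropeptide transcript Pmch was 187.2 in SHR 4 against 3.4 to 65.4 in the other arrays, but 6.9 and 17.5 in dehydrated 1 and 2. Another, Hcrt, was 30.6 in SHR 4, within the 0.8 to 224.6 of the other arrays. What these values mean for the SHR 4 pool was not tested. No other tissue content of the pools and no other technical explanation was tested, nor any for the division by array number in both strains.

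Other divisions of the arrays bear on the remaining counts. For fasted and control arrays 3 of 100 splits, of 126 possible ones, gave as many as the 4 calls. The share lies under 5%, but it does not exclude chance, since other splits gave as many calls and not every possible split was run. The highest other split (control 2, 3 and 4 with fasted 1 and 2) gave 9, more than the real one. None of the 4 calls was kept in every alternative. For dehydrated and control arrays 1 of 35 splits, the real one with 31, gave as many, and the highest other (control 3 with dehydrated 1, 2 and 3) gave 4. For dehydrated and fasted arrays 2 of 100 splits, of 126 possible ones, gave as many as 6. The highest other split there, dehydrated 1, 2 and 3 with fasted 4, gave 23, several times the real count, which points to a structure of the samples. It divided arrays with high from arrays with low choroid plexus marker means. These were 0.35, 0.51, 1.28 and 1.46 in the 4 arrays, -0.65 in dehydrated 4 and -0.93 to -0.49 in the other fasted arrays. The highest other split of dehydrated and control arrays divided them likewise, with control 3 at 1.11 and the other controls at -0.59 to -0.36. Whether choroid plexus content made these calls was not tested.

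Single arrays stood apart from their group in 23 of 309 groups of values, where chance gives about 5%. The measure is the gap to the nearest other array as a share of the group's range. In WKY these were Actr8 in WKY 1 (share 0.83, signal 93.9 against 107.6 to 110.5), Adipor2 in WKY 5 (0.71, 58.2 against 79.9 to 90.4), Agtrap in WKY 4 (0.8, 6.1 against 29.5 to 38.4), Col1a2 in WKY 4 (0.78, 1589.6 against 1981.5 to 2111.1), Lst1 in WKY 2 (0.71, 144.2 against 74.2 to 90.3), Me1 in WKY 2 (0.79, 1151.7 against 1027.1 to 1051.7) and Tstd1 in WKY 2 (0.74, 77.2 against 99 to 107.6). In SHR it was Th in SHR 3 (0.76, 308.7 against 370.7 to 393).

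Control 3 stood apart for Olfml3 (share 0.87, signal 462.3 against 576 to 595.2), Acadvl (0.92, 351.7 against 408 to 413.5), Ldha (0.93, 1872 against 2273.1 to 2306), Tcn2 (0.86, 1094.9 against 1307.6 to 1344.4) and Klhl24 (0.91, 85 against 70.1 to 71.4), and in the marker means of choroid plexus (0.86, 1.11 against -0.59 to -0.36) and cholinergic motor neurons (0.84, 0.09 against -0.29 to -0.23). Control 1 did so for Tcp11l2 (0.91, 423.8 against 362.5 to 367.9) and control 2 in the fibroblast marker mean (0.91, 0.42 against 0.1 to 0.13). Among fasted arrays fasted 5 stood apart for Nmu (0.82, 130.6 against 104.7 to 108.9) and fasted 4 in the choroid plexus marker mean (0.82, 1.46 against -0.93 to -0.49). Among dehydrated arrays dehydrated 1 stood apart for Acsbg1 (0.94, 553.6 against 610.8 to 614.9), Avpr1a (0.95, 39.8 against 52 to 52.7) and Cdh1 (0.92, 93.2 against 85.4 to 86), and dehydrated 2 for Fos (0.83, 107.2 against 67.2 to 72.9).

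By the direct test, dehydrated and fasted arrays differed at 6 probe sets: 1 of Bdnf (difference 1.19, adjusted p = 1.44e-05, over the alternatives 2.62e-06 to 0.0743), 1 of Klhl24 (-0.77, 0.00128, 0.00034 to 0.288), Pbxip1 (-0.56, 0.00834, 0.00491 to 0.308), Sh3bgrl1 (0.45, 0.0187, 0.00653 to 0.371) and 2 without a single symbol (-0.67 and -0.44, 0.0155 and 0.0187). The calls of Bdnf, whose second probe set was dim, and of Klhl24 ended when the probe sets of the gene were averaged.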

How the results depend on the processing

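The fits without control 2 and dehydrated 2 together, without dehydrated 1 and 2 together, with the choroid plexus marker mean as covariate, with arrays 1 and 2 of each strain against 3 to 5 as a block, and with the peptide list taken without Avp and Oxt were chosen after the data were seen.

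No named gene or list that passed reversed its direction in any alternative run. Of the named genes past the threshold, 49 of 63 stayed past it in every alternative for SHR and WKY, 0 of 4 for fasting, 1 of 28 (Bdnf) for dehydration and 0 of 4 for dehydrated against fasted arrays. None of the 5, 7, 7 and 5 lists that passed did so in every alternative, and the estimated correlation ended each call. Over the alternatives, 67 of 1587 gene values lost a call for SHR and WKY, 29 of 549 for fasting, 274 of 956 for dehydration and 20 of 547 for dehydrated against fasted arrays. A call was gained in 3, 10, 0 and 5 of them.

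The SHR and WKY count of 942 fell to 514 when the probe sets of a gene were averaged, with 484 of the genes shared, where fewer units were tested (10476). It was 755 to 966 under the other planned settings apart from the replicate block and the 3' to 5' covariate (698), 741 to 1012 with 1 array left out (lowest without SHR 3), and 1168 with arrays 1 and 2 against 3 to 5 as a block.

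The fasted count of 4 became 2 without a filter, 2 with eBayes without trend and robust, 0 with control replicates 3 and 4 alone (fewer arrays) and 2 without control 2 and dehydrated 2 together. With 1 array left out it ran from 2 to 6, and with the 3' to 5' covariate 2 of the 4 calls remained. The dehydrated count of 31 became 15 without a filter, 10 with eBayes without trend and robust, 74 with all 23 arrays in 1 model, 2 with control replicates 3 and 4 alone, 6 without control 2 and dehydrated 2 together, 20 with the choroid plexus marker mean as covariate and 2 without dehydrated 1 and 2 together. With 1 array left out it ran from 9 to 42, and with the 3' to 5' covariate 24 of the 31 calls remained. The dehydrated against fasted count of 6 became 3 with eBayes without trend and robust, 2 with the 3' to 5' ratio as covariate, 2 with the mean of a gene's probe sets and 3 without dehydrated 1 and 2 together. It ran from 2 to 10 with 1 array left out. Fits with arrays left out have fewer samples, and the cause of these changes was not tested. Without dehydrated 1 and 2 together the fibroblast, cholinergic, fatty acid oxidation and oxidative phosphorylation lists no longer passed for dehydration, nor did fatty acid oxidation and oxidative stress for dehydrated against fasted arrays.

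The covariance of fasting and dehydration changes fell from 0.0117 to 0.00283 and 0.00108 with the controls split, 1 and 2 for one treatment and 3 and 4 for the other and the reverse, by the loss of the shared arrays, and was 0.0119 with quantile normalization.

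The replicate numbers do not pair the samples throughout, but arrays 1 and 2 of SHR and WKY shared part of their deviations. For these strains the deviations of arrays with the same number correlated at 0.162, 0.28, 0.028, -0.002 and 0.039, best with their own number only for 1 and 2. In the other comparisons the correlations were -0.171 to 0.056. The replicate block gave 1073, 3, 15 and 1 calls in the 4 comparisons.

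Signal over background limits what can be seen. Probe sets below the 40th percentile, such as those of Lepr, were not tested, and at a log2 change of 0.5 the simulated recovery was 52.2 to 74.6%.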

Other observations

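The comparisons of Sprague Dawley control arrays with the strains, the neighbour runs named here and the genes outside the naming rule were chosen only after the results were seen.

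Some large strain differences sat at 1 of several probe sets of a gene. Igfbp5, which binds insulin-like growth factors, had 1758.1 ± 348.4 in SHR and 535.8 ± 171.7 in WKY at 1 probe set (log2 1.73, adjusted p = 0.00323), while its other 4 differed by -0.09 to -0.52 and did not pass. A probe set of the class II gene RT1-Ba rose by 1.98 (adjusted p = 2.14e-06) where 3 others differed by -0.12 to -0.37, and neither gene passed when its probe sets were averaged, the highest adjusted p over the alternatives (2.24e-06 to 0.644 for Igfbp5, 2.02e-09 to 0.213 for RT1-Ba). Zbtb20, a transcriptional repressor of brain development, fell by 1.82 at 1 probe set (adjusted p = 2.83e-10), with its other 4 at -0.29 to 0.26. By contrast, Rab8b, a vesicle transport GTPase, fell at both of its probe sets, by 1.00 and 0.74 (adjusted p = 7.32e-08 and 5.15e-06). Rlbp1, a retinal-binding protein of glia, had 76.1 ± 12.1 in SHR and 168.9 ± 25.8 in WKY (2.01-fold lower, adjusted p = 6.89e-06). The immunoproteasome subunit Psmb8 rose by 0.43 (adjusted p = 0.00355). Toll-like receptor Tlr2 fell by 0.37 (adjusted p = 0.0375, over the alternatives 0.0161 to 0.231), and without SHR 1, 2, 4 or 5 (0.0678, 0.0709, 0.0839 and 0.0653) or WKY 1, 2, 3 or 5 (0.0985, 0.0864, 0.0864 and 0.0675) it did not pass. Nor did Tlr2 pass with the 3' to 5' ratio as covariate, without a filter or with all 23 arrays in 1 model.

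Genes of the major histocompatibility complex that are neighbours among the tested genes passed in runs on chromosome 20, where 31 of 301 placed genes passed (10.3%), the highest share of any chromosome. Ltb, Lst1 and Aif1 were lower by 0.42, 1.07 and 0.39 in SHR. The other runs there were mixed, with RT1-CE16 at 1.95 beside RT1-CE12 at -0.36, RT1-CE10 at -0.56 and RT1-CE5 at -1.02, and with RT1-Ba at 1.98 beside RT1-Bb at -1.38 and Psmb8 at 0.43. On chromosome 5 a run of Matn1 (log2 0.80), Ptpru (0.64) and Mecr (0.41) was higher, and one of Plekhf2 (-0.65), Ccne2 (0.39) and Dpy19l4 (0.54) was mixed, as were the runs on chromosomes 2 and X. In another strain, that of the Sprague Dawley controls, the signal lay nearer to SHR at 33 and nearer to WKY at 23 of the 56 probe sets with at least 2-fold differences, and at 484 and 458 of all 942. The controls had 23.4 ± 9.1 for Ephx2, near WKY, and 3310.6 ± 667.3 for Igfbp5, above SHR (n = 4). No test sets these controls against the strains, since strain and array series differ together.

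Ttr, transthyretin, the main secretory product of the choroid plexus, varied far more between Sprague Dawley arrays than between strains. It was 6558.6 in control 3, 6342.6 in fasted 4, and 2714.8, 4206.5 and 7953.2 in dehydrated 1, 2 and 3, while the other Sprague Dawley arrays had 152.1 to 855.5. The SHR and WKY arrays had 44.2 to 189.1. The 6 measured choroid plexus markers did not pass as a list in any comparison, with adjusted p = 0.922, 0.983, 0.267 and 0.246 for SHR and WKY, fasting, dehydration, and dehydrated against fasted arrays. For SHR and WKY their median was -0.14 and their mean -0.03, while the test pointed upwards, with Enpp2 at 0.74.

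The fry and camera tests passed different lists. Of the lists that camera passed at the preset correlation, fry passed none for dehydration (adjusted p = 0.0964 to 0.236) or for dehydrated against fasted arrays (0.109 to 0.351), only the insulin and FOXO list for fasting (0.0642 to 0.532 for the others), and all but the interferon list (0.286) for SHR and WKY. It also passed lists that camera did not. For SHR and WKY these were the hypertension candidates (upwards, adjusted p = 0.00347) and fatty acid oxidation (upwards, 0.0294), and for dehydrated against fasted arrays the insulin and FOXO list (downwards, 0.0302), where camera gave 0.256, 0.0748 and 0.139. For fasting the insulin and FOXO list had 0.0283 by fry and 0.0338 by camera, upwards in both. Only 1 blood marker was measured, and only 2 markers of cholinergic motor neurons in the strain comparison, so that these were not tested.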
